A study of Homo sapiens with 2 samples.

How the data were processed

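Total RNA of SK-HEP-1 cells with a lentivirus for MYOD1 and of cells with the empty vector was collected after 12 days, 1 library per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA, HISAT2, featureCounts 1.5.0-p3 and the build GRCh38, without saying which step each served. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The values analysed are the FPKM the authors deposited for 62745 gene rows with names, coordinates, lengths and biotypes, and coordinates are given as in that table. The columns were matched to the libraries by the names in the labels.

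Multiplying FPKM by gene length gave whole numbers of reads for 100% of values above 0, within 0.02 reads, at a divisor of 17076720 reads for the control library and 14768540 for the MYOD1 library. The reads so obtained summed to 17850059 and 15322714, so the authors' divisors were 95.7% and 96.4% of these sums, and the reason for the gap is not given in the sources used here. These reads served for depth, for exact conditional binomial 95% intervals of FPKM ratios, for exact Poisson limits of single values and for a floor of 3 reads per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a library had 0 reads the ratio was taken against its floor and stated as a lower bound, and where it had 1 to 3 reads the ratio is given with its interval.

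Differences are log2(FPKM + 1) in the MYOD1 library minus the control library, with a pseudocount of 1, over gene rows with an FPKM of at least 1 in at least 1 library. No test across replicates was possible with 1 library per group, and no p-values are given. Genes were counted by a size of 4-fold and list members by a size of 2-fold on this scale. The 43 gene lists, the rule for named genes and 9 kinds of alternative setting were fixed before the data were examined. All 986 list members were matched to rows by gene name; 2 lists had no member past the filter. Each list's median was placed among medians of 10000 random lists of the same size, drawn from the passing genes within 20 bins of mean log2(FPKM + 1). The percentile describes these libraries and is not a p-value. With libraries at 0 reads set to the floor, the largest move of any median was 0.23, in the muscle non-coding RNA genes.

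The named genes were MYOD1; for each list up to 3 passing members with the largest difference in the direction of the list's median and the 1 most different the other way if at least 2-fold; MYOG, MYF5, MYF6, MEF2C, MYMK, MYMX, DES, CKM, CDKN1A, ID1 and ID3; and the 10 largest and 10 smallest differences among protein-coding genes with an FPKM of at least 10 in at least 1 library. This gave 146 genes, some of which are not reported here. A gene named outside this rule, such as MYL1, CHAT and NGFR-AS1, was chosen after its values were seen.

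Alternatives were a pseudocount of 0.1 or 5, no filter, a filter of 5 FPKM, rescaling to TPM, setting the median gene to 0, protein-coding genes only, random lists not matched on expression and a size of 2-fold. Added after seeing the data were primary chromosomes only, scaling without mitochondrial reads, at least 20 reads over both libraries, and removal of trends with GC content and gene length by lowess with a span of 0.3. GC content came from the longest GENCODE release 29 transcript of each gene, found for 95.9% of passing rows. The counting of genes and the list percentiles were tested on simulated reads of these 2 libraries, with 12299 genes past the filter. Changed genes and lists were drawn only from protein-coding genes with a mean of at least 5 FPKM. Of 200 genes changed 8-fold, 95% were recovered at the 4-fold size, and 0 unchanged protein-coding genes and 3 other rows were called. Of 10 lists shifted 2-fold, 10 lay above percentile 97.5, and 0 of 50 unshifted lists lay outside the central range. The simulation held counting error only. It therefore does not cover variation between cultures, nor recovery of genes at lower FPKM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

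Reads are sparse in 1 region. Of 202 protein-coding genes on chromosome 6 between 28 and 34 Mb, the major histocompatibility region, 75.2% had no reads in either library, against 26.5% of 19768 elsewhere on the primary chromosomes. Levels of genes in that region, such as the ribosomal protein gene RPS18 (0.99 and 2.36 FPKM), are not interpreted.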

Results

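RNA was sequenced from SK-HEP-1, an established human line that the labels describe as hepatocellular carcinoma and that is widely reported to have endothelial rather than hepatocyte traits. Cells carrying a lentivirus for forced expression of MYOD1, the basic helix-loop-helix factor that starts the skeletal muscle programme, were compared with cells carrying the empty vector after 12 days. The labels state that MYOD1 cells had changed in phenotype by then, and the comparison asks which transcripts differed between these cultures. There was 1 library per group. The FPKM values corresponded to 17850059 assigned reads in the control library and 15322714 in the MYOD1 library. Of 62745 gene rows, 21069 had reads in the control library and 21514 in the MYOD1 library. Mitochondrially encoded genes took 5.40% of reads in the control library and 8.05% in the MYOD1 library. With no replicates, every difference describes these 2 libraries only. Fold values of single genes are ratios of FPKM, and their 95% intervals cover counting error only, not the variation between cultures. Medians of gene lists are differences of log2(FPKM + 1), MYOD1 minus control, which understate the difference of genes at low FPKM. Members of lists are counted on that scale, so a gene with an FPKM ratio beyond 2-fold can count as neither.

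MYOD1 (ENSG00000129152, chromosome 11, 17719571 to 17722136, plus strand, GRCh38) had 0 reads in the control library and 15072 reads in the MYOD1 library. Its level there was 566 FPKM (95% counting interval 557 to 575), at least 5809-fold higher than the floor of 3 reads in the control library. The values are per gene and do not separate vector-borne from endogenous MYOD1 transcripts.

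Across the 12912 gene rows with an FPKM of at least 1 in either library, 205 were at least 4-fold higher and 71 at least 4-fold lower in the MYOD1 library on the log2(FPKM + 1) scale. Higher rows were 74.3% of these. Once trends with GC content and gene length were removed, they were 59.6% (164 higher, 111 lower), over only the 12385 rows with a GC value. Among 10315 protein-coding genes, 122 were higher and 26 lower by this size, and the counting interval of each lay beyond 2-fold. Small RNA gene rows, with a median length of 103.5 bases, contributed 43 higher and 30 lower rows. Of the 205 higher rows, 72 had no reads in the control library, and 30 of the 71 lower rows had none in the MYOD1 library. With those libraries set to the floor of 3 reads, 151 rows were higher and 45 lower, against 118 and 26 among protein-coding genes. The pseudocount set the counts of all rows, with 770 higher and 381 lower at a pseudocount of 0.1 and 56 higher and 12 lower at 5. The libraries correlated across genes (Pearson r = 0.909, Spearman rho = 0.894), and genes are not independent replicates.

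**Figure D1:**
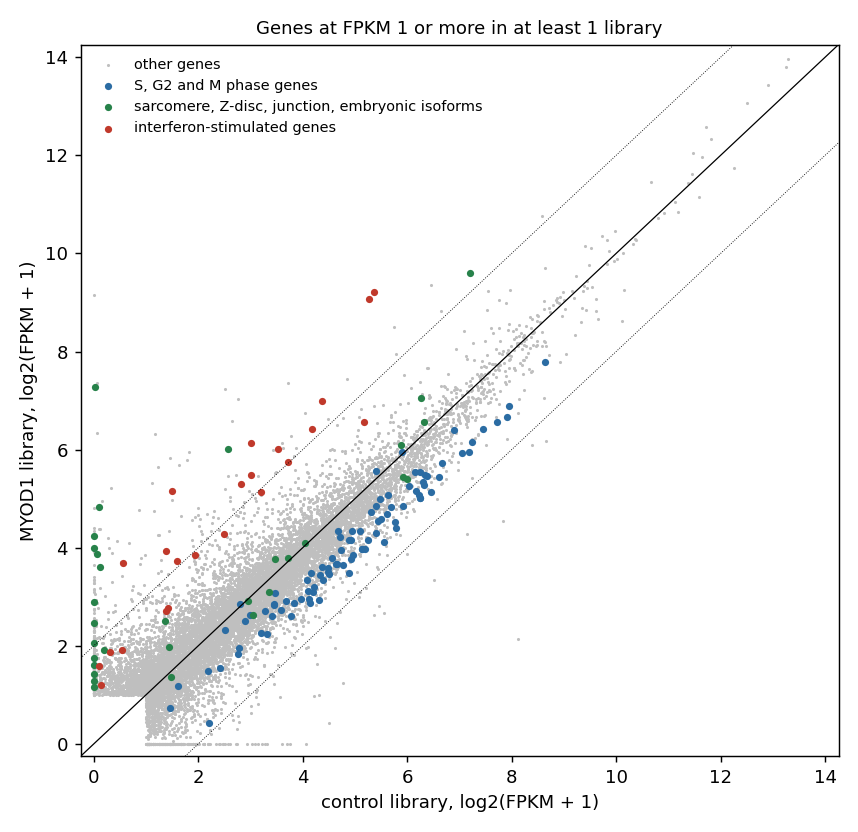
Each point is a gene row with an FPKM of at least 1 in either library, with log2(FPKM + 1) in the control library on the x axis and in the MYOD1 library on the y axis. The solid line marks equal values and the dotted lines a 4-fold difference; interferon-stimulated genes (red) lie above the solid line, most cell cycle genes (blue) below it, and genes of the sarcomere, Z-disc, junction and embryonic isoform lists (green) range from near the line to the left edge, where control values are at or near 0.

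Skeletal muscle genes were higher in the MYOD1 library as a group. The 13 lists of muscle genes joined here, each fixed before the data were examined, held 239 genes, of which 100 passed the filter; the muscle progenitor list and the IGF and myostatin axis list, with medians of -0.22 and -0.38, are not among them, and with both added the median below is 0.28 over 120 genes. Of the 100 passing genes, 42 were at least 2-fold higher, 1 was at least 2-fold lower and 57 were neither. Members with 0 reads in the control library could pass the filter only as higher, so these counts depend on the filter. Over the 100 passing genes the median log2 difference was 0.42, where 95% of 10000 random lists matched on expression had medians from -0.14 to 0.10. Among the 122 protein-coding genes at least 4-fold higher, 21 were muscle list members, where 1.16 would be expected from independent lists.

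Myogenic transcription factors had a median difference of 1.13, at percentile 100 of the random lists, with 6 of 10 passing members at least 2-fold higher and 4 neither; it was 0.45 without the filter on low values. SMARCD3, a chromatin remodelling subunit used in muscle and heart development, was at 1.33 FPKM in the control library and 10.1 in the MYOD1 library, a 7.61-fold difference (6.23 to 9.37). MEF2D was 2.78-fold higher (2.60 to 2.97) and PITX3 3.84-fold higher (2.55 to 5.94). MEF2C, a partner of the myogenic factors, went from 3 reads to 192, a ratio of 74.0 (24.9 to 362), but reached only 1.11 FPKM. The other myogenic regulatory factors were at or near the detection limit. MYOG, which drives terminal differentiation, had 0 reads in the control library and 4 in the MYOD1 library, 0.18 FPKM with an upper 95% limit of 0.46. MYF5 and MYF6 had no reads in either library, where the floor of 3 reads corresponds to 0.13 and 0.15 FPKM in the MYOD1 library.

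Some contractile and Z-disc genes were much higher in the MYOD1 library, while other detected members were near equal or lower. For sarcomere thick and thin filament genes the median was 1.26 (percentile 100), with 5 of 10 passing members at least 2-fold higher and 5 neither, while 25 of the 35 members lay below the filter. TNNI1, the slow skeletal troponin I, had 0 reads in the control library and 17.8 FPKM in the MYOD1 library, at least 761-fold higher. TNNC1, the slow and cardiac troponin C, was at 14.8 FPKM (at least 96.4-fold higher), and the myosin-binding protein gene MYBPH at 6.44 FPKM (at least 66.7-fold higher). Z-disc, M-band and titin-associated genes had a median of 1.52 (percentile 100), with 9 of 14 passing members higher, 5 neither and 25 of 39 below the filter. KLHL41, a kelch protein of the sarcomere, was at 0.07 FPKM in the control library from 3 reads and at 27.3 FPKM in the MYOD1 library, a ratio of 407 (139 to 1977). TRIM55, a titin-binding ubiquitin ligase, was at 13.6 FPKM against 2 control reads (ratio 358, 98.7 to 2962), and SYNPO2 was 139-fold higher (95.4 to 211). DES, the muscle intermediate filament gene, remained low, with 1 read in the control library and 0.38 FPKM in the MYOD1 library (ratio 16.2, 2.46 to 684). Without the filter on low values the medians were 0.083 for sarcomere genes and 0.086 for Z-disc genes, so the positive medians depend on the filter. With libraries at 0 reads set to their floor, the medians over passing members were 1.25 and 1.37.

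**Figure D2:**
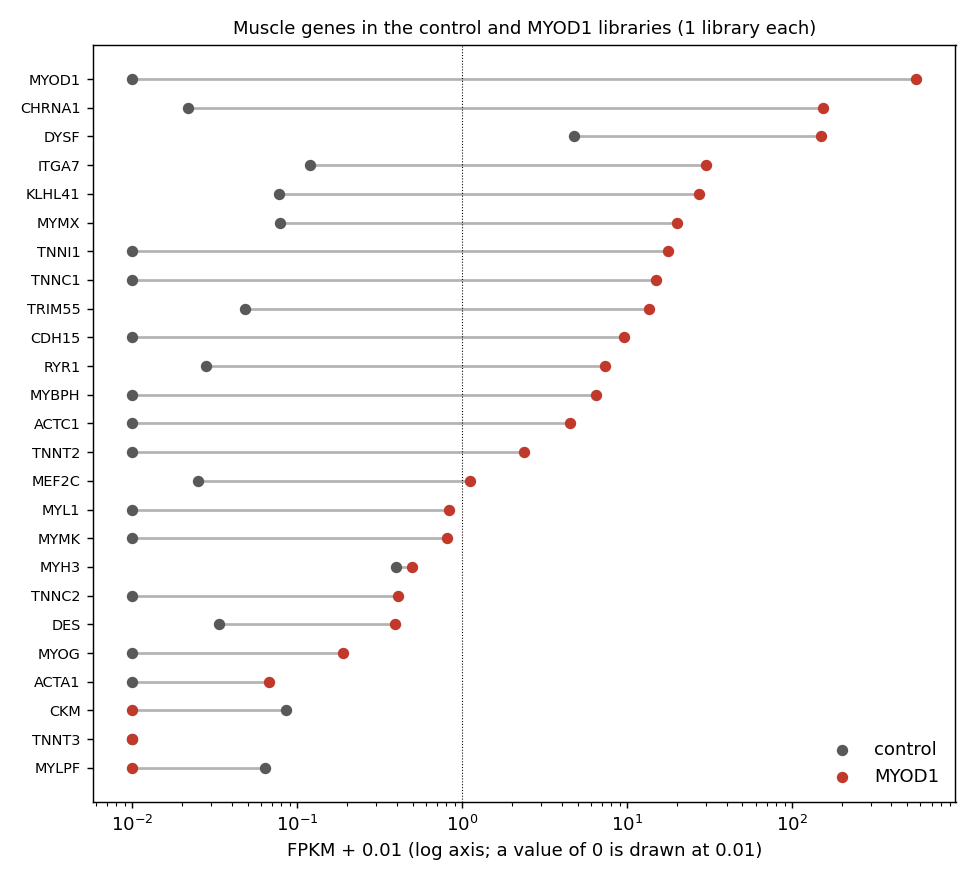
FPKM + 0.01 of 25 muscle genes on a log axis in the control library (grey) and the MYOD1 library (red), 1 library each; a value of 0 is drawn at 0.01 and the dotted line marks 1, and the points of TNNT3 coincide at 0. MYOD1, CHRNA1 and DYSF exceed 100 FPKM in the MYOD1 library, whereas MYOG, ACTA1, DES, CKM, TNNT3 and MYLPF stay below 1; genes were picked for display after their values were seen.

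The embryonic, slow fibre and fast fibre isoform lists differed in detection. Embryonic isoforms had a median of 2.46 (percentile 99.99) with 3 of 3 passing members higher and 5 of 8 members below the filter. Of these 3, 2 had 0 reads in the control library, so the filter fixed their direction. CHRNA1 (ENSG00000138435, chromosome 2, 174747592 to 174787935, minus strand), the acetylcholine receptor alpha subunit, had 1 read in the control library and 11289 in the MYOD1 library, where it reached 154 FPKM (ratio 13053, 2342 to 515625). ACTC1, the cardiac actin used in embryonic muscle, was at 4.49 FPKM (at least 58.6-fold higher), and TNNT2 at 2.36 FPKM (at least 98.3-fold higher). Slow fibre isoforms had a median of 0.74 (percentile 99.4), with 3 of 6 passing members higher and 3 neither, and MYOZ2 was at least 20.8-fold higher at 1.43 FPKM. The embryonic median exceeded the slow fibre median by 1.71. With libraries at 0 reads set to their floor, these medians were 2.35 and 0.70. The embryonic median rests on 3 genes, and each is in another list too. CHRNA1 is also a neuromuscular junction list member, and ACTC1 and TNNT2 are sarcomere list members. Of the 3 higher slow fibre genes, TNNI1 and TNNC1 are also in the sarcomere list and MYOZ2 in the Z-disc list. The percentiles of these lists are therefore not separate support. TNNI1 and TNNC1 of the slow fibre list reached 17.8 and 14.8 FPKM, above ACTC1 and TNNT2. The gap between medians therefore does not show that embryonic isoforms were higher than slow ones. Without the filter the embryonic median was 1.01, the slow fibre median 0.074 and their difference 0.93, and at a pseudocount of 5 the difference was 0.65. None of the 13 fast fibre isoforms passed the filter, and the highest value among them was 0.82 FPKM, for MYL1 in the MYOD1 library.

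Fusion genes went both ways. Their median was -0.17 (percentile 20.1) while their mean was 0.67, and 4 of 13 passing members were at least 2-fold higher, 1 was lower and 8 were neither. MYMX, the fusogenic micropeptide, had 1 read in the control library and 19.9 FPKM in the MYOD1 library (ratio 290, 51.6 to 11509). MYMK, its membrane partner in fusion, had 12 reads against 0, 0.80 FPKM and at least 4.63-fold higher. ITGA7, the laminin receptor of muscle, was 274-fold higher (171 to 472) at 30.1 FPKM. DOCK5 was 2.26-fold lower (2.11 to 2.42), KIRREL3 2.38-fold lower (2.05 to 2.77) and CDH2, N-cadherin, 3.41-fold lower (2.58 to 4.55).

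Genes of the muscle membrane and its excitation were higher in part. Neuromuscular junction genes had a median of 1.14 (percentile 99.96; 1.10 with libraries at 0 set to their floor), with 4 of 7 passing members higher, 3 neither and 9 of 16 members below the filter. It was 0.23 without the filter, 0.065 with a filter of 5 FPKM and 0.32 at a pseudocount of 5; CHRND was at 3.16 FPKM (at least 56.3-fold higher) and DOK7 at 1.24 FPKM (at least 28.5-fold higher). Excitation-contraction coupling genes had a median of 0.46 (percentile 96.8), with 4 of 12 higher and 8 neither. RYR1, the sarcoplasmic calcium release channel, was 406-fold higher (174 to 1252) at 7.30 FPKM, CACNG6 was 7.90-fold higher (6.89 to 9.09), and STAC3 was at least 24.3-fold higher. Dystrophin complex and membrane repair genes had a median of 0.16 (percentile 86.3), with 3 of 13 higher and 10 neither. DYSF, the membrane repair protein dysferlin, was at 4.73 FPKM in the control library and 150 FPKM in the MYOD1 library, a 31.8-fold difference (29.4 to 34.3). SGCA had 1 control read (ratio 89.0, 15.5 to 3562) and SNTB1 was 3.67-fold higher (3.02 to 4.49).

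Muscle metabolism genes had a median of 0.40 (percentile 96.5), with 4 of 9 passing members at least 2-fold higher and 5 neither. VGLL2, a TEAD cofactor of muscle, was 44.9-fold higher (26.5 to 82.7), GATM 50.7-fold (28.1 to 102) and ENO3, the muscle enolase, 3.94-fold (3.10 to 5.06). CKM, the muscle creatine kinase, was not among them, with 2 reads in the control library and 0 in the MYOD1 library. Muscle RNA-binding and splicing factors had a median of 0.10 (percentile 85.5), with 1 of 10 higher and 9 neither. The higher member was RBM24, 6.43-fold higher (5.88 to 7.04) at 62.8 FPKM; RBFOX2 was 1.69-fold higher (1.49 to 1.90) and RBM20 1.39-fold higher (1.13 to 1.71). Both passing muscle non-coding RNA genes were higher (median 2.54, percentile 99.9; 2.31 with the library at 0 set to its floor). LINCMD1 was at 14.1 FPKM from 96 reads (at least 37.0-fold higher), and MIR503HG was 2.33-fold higher (2.14 to 2.54). Medians of metabolism and RNA-binding genes turned negative, to -0.14 and -0.08, when only members at 5 FPKM or more were kept.

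Muscle progenitor genes had a median of -0.22 (percentile 21.8), with 2 of 7 passing members at least 2-fold higher, 1 lower and 4 neither. Of the 18 members, 11 lay below the filter and 9 had no reads in either library, among them PAX3 and PAX7. MET, the hepatocyte growth factor receptor, was 2.96-fold lower (2.81 to 3.11), FGFR1 2.17-fold lower (1.998 to 2.36) and ITGB1 1.36-fold lower (1.33 to 1.40). CD34 was 25.0-fold higher (15.97 to 41.3) at 3.17 FPKM. IGF and myostatin axis genes had a median of -0.38 (percentile 1.53), with 1 of 14 higher, 3 lower and 10 neither. IGFBP3, a binding protein for insulin-like growth factors, was at 403 FPKM in the control library and 71.4 in the MYOD1 library, 5.65-fold lower (5.48 to 5.82). IGFBP2 was 3.28-fold lower (2.68 to 4.06) and IGFBP6 2.23-fold lower (2.02 to 2.46), while FST, the myostatin antagonist follistatin, was 3.93-fold higher (3.49 to 4.43).

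Cell cycle genes were lower in the MYOD1 library. Of 93 passing S, G2 and M phase genes, 38 were at least 2-fold lower, 0 were at least 2-fold higher and 55 were neither, and 90 lay below 0. Their median was -0.93, or 1.91-fold lower, where 95% of random lists lay between -0.22 and 0.00. S phase genes had a median of -0.89 (percentile 0), with 14 of 43 lower and 29 neither. UHRF1, which maintains DNA methylation at replication, was 2.81-fold lower (2.64 to 2.996) and RRM2, a ribonucleotide reductase subunit, 2.55-fold lower (2.46 to 2.64). UBR7 was 10.4-fold lower (6.41 to 17.8) at 3.60 FPKM in the control library. G2 and M phase genes had a median of -0.97 (percentile 0), with 24 of 50 lower and 26 neither; NEK2 was 2.81-fold lower (2.53 to 3.13), cyclin A2 (CCNA2) 2.69-fold lower (2.48 to 2.91) and NUF2 2.84-fold lower (2.51 to 3.22). These genes differed alongside the mitochondrial read share, which was 5.40% in the control library and 8.05% in the MYOD1 library. Scaled without mitochondrial reads, the S phase median was -0.86 and the G2 and M phase median -0.93. That setting covers scaling only.

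Cell cycle inhibitors and cyclin D genes had a median of 0.14 (percentile 88.3), with 2 of 10 passing members higher, 1 lower and 7 neither. CDKN1A, which encodes the inhibitor p21, was at 134 FPKM in the control library and 340 in the MYOD1 library, 2.53-fold higher (2.46 to 2.61). CCND2, cyclin D2, was 32.8-fold higher (23.6 to 46.8) at 8.88 FPKM and CCND3 1.38-fold higher (1.31 to 1.46), whereas CDKN2C was 2.64-fold lower (2.30 to 3.04). Targets of p53 had a median of 0.37 (percentile 99.98), with 2 of 21 higher, CDKN1A and TP53INP1, and 19 neither. TP53INP1 was 2.69-fold higher (2.39 to 3.03); BBC3, counted as neither, had an FPKM ratio of 2.11 (1.74 to 2.57). ID, HES and Notch genes had a median of 0.70 (percentile 99.99), with 5 of 14 higher, 1 lower and 8 neither. HEYL, a Notch-responsive repressor, was 14.9-fold higher (11.5 to 19.8), BHLHE40 4.63-fold (4.16 to 5.15) and ID2 4.26-fold (3.67 to 4.96). ID1, which blocks MYOD1 dimers with E proteins, was 2.44-fold lower (2.10 to 2.83), and ID3 had no reads in either library.

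Markers of the starting line and of other lineages were mixed. The 8 lists of other lineages held 43 passing genes, of which 8 were at least 2-fold higher, 8 lower and 27 neither, with a median of 0.16 (percentile 97.1, 95% of random lists from -0.22 to 0.17). Smooth muscle, cardiac and oncofetal genes are not among these 8 lists. Some genes, MEF2C among them, belong both to these lists and to the muscle lists. The muscle median exceeded the other lineages by 0.26, and by 0.15 without the filter. The lists were fixed beforehand, but which of them to join was not, and the gap depends on that choice. With the progenitor and the IGF and myostatin axis lists added, the muscle median was 0.28. None of 26 hepatocyte markers passed the filter in either library, 18 had no reads, and the highest value was 0.71 FPKM. Oncofetal liver and hepatobiliary markers had a median of 0.01 (percentile 64.4) and a mean of -0.31, with 1 of 7 lower and 6 neither. KRT7 was 2.84-fold lower (2.27 to 3.57), while KRT19 was 1.20-fold higher (1.18 to 1.23) and SOX9 was at 70.4 and 74.3 FPKM; CD24 was at 1.85 FPKM in the control library and 2.34 in the MYOD1 library, a ratio whose interval included 1 (0.95 to 1.68). Endothelial markers had a median of -0.06 (percentile 36.9) and a mean of 0.11, with 1 of 6 higher, 1 lower and 4 neither. Of the 23 endothelial markers, 17 lay below the filter and 7 had no reads in either library. ENG, endoglin, was 2.17-fold lower (2.01 to 2.35), SOX18 1.60-fold lower (1.19 to 2.16) and EGFL7 1.38-fold lower (1.21 to 1.56), and CLDN5 was at 1.68 FPKM against 0 (at least 32.8-fold higher). The oncofetal median was -0.038 in TPM and -0.33 with a filter of 5 FPKM, and the endothelial median was 0.030 with GC and length trends removed and -0.75 with a filter of 5 FPKM.

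Fibroblast and matrix genes had a median of -0.10 (percentile 36.9), with 1 of 21 higher, 5 lower and 15 neither, and 0.0041 with GC and length trends removed. FN1, fibronectin, was 3.16-fold lower (3.04 to 3.28), LOXL2 2.67-fold lower (2.55 to 2.80) and COL4A2 3.03-fold lower (2.75 to 3.33), while the membrane collagenase gene MMP14 was 3.33-fold higher (3.18 to 3.48). Smooth muscle genes had a median of 0.18 (percentile 94.6), with 1 of 11 higher and 10 neither; the higher member was SYNPO2, TPM2 was 1.73-fold higher (1.66 to 1.80) and CALD1 1.89-fold higher (1.72 to 2.09). The Z-disc median exceeded the smooth muscle median by 1.33, but by only 0.015 without the filter and 0.35 at a pseudocount of 5. Cardiac-enriched genes had a median of 0.33 (percentile 87.2), with 3 of 8 higher, 1 lower and 4 neither; ACTC1 and TNNT2 are shared with the embryonic list, and NPPB, the natriuretic peptide B gene, went from 11.9 FPKM to 0, at least 41.5-fold lower. Cartilage and bone genes had a median of 1.29 (percentile 99.99), with 4 of 6 higher and 2 neither, and 0.69 without the filter. ALPL, alkaline phosphatase, was 18.1-fold higher (15.9 to 20.5) at 94.7 FPKM, RUNX2 4.43-fold (4.01 to 4.90) and MATN3 5.88-fold (4.05 to 8.77). The remaining higher member was MEF2C, shared with the myogenic transcription factor list. The median lies between its difference of 1.05 and that of MATN3, 1.53.

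Remaining lineage lists had few detected members. Neuronal genes had a median of 0.73 (percentile 95.8), with 2 of 4 higher and 2 neither, and -0.074 when only members at 5 FPKM or more were kept; SYT1 was 16.6-fold higher (9.83 to 30.1), SYP 6.79-fold (4.62 to 10.3) and INA 1.30-fold (1.11 to 1.52). Epithelial markers had a median of -0.24 (percentile 23.2), with 1 of 3 lower and 2 neither, and 0.27 with a filter of 5 FPKM; KRT15 was 1.27-fold lower (1.05 to 1.53). The single passing adipocyte gene, LIPE, differed by -0.19 (percentile 36.5), and its interval included equality. Leukocyte markers had a median of -0.87 (percentile 3.71) over 2 passing genes, and CD74, the invariant chain of major histocompatibility complex class II, was 4.37-fold lower (3.97 to 4.82); without the filter on low values the median was 0.047.

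**Figure D3:**
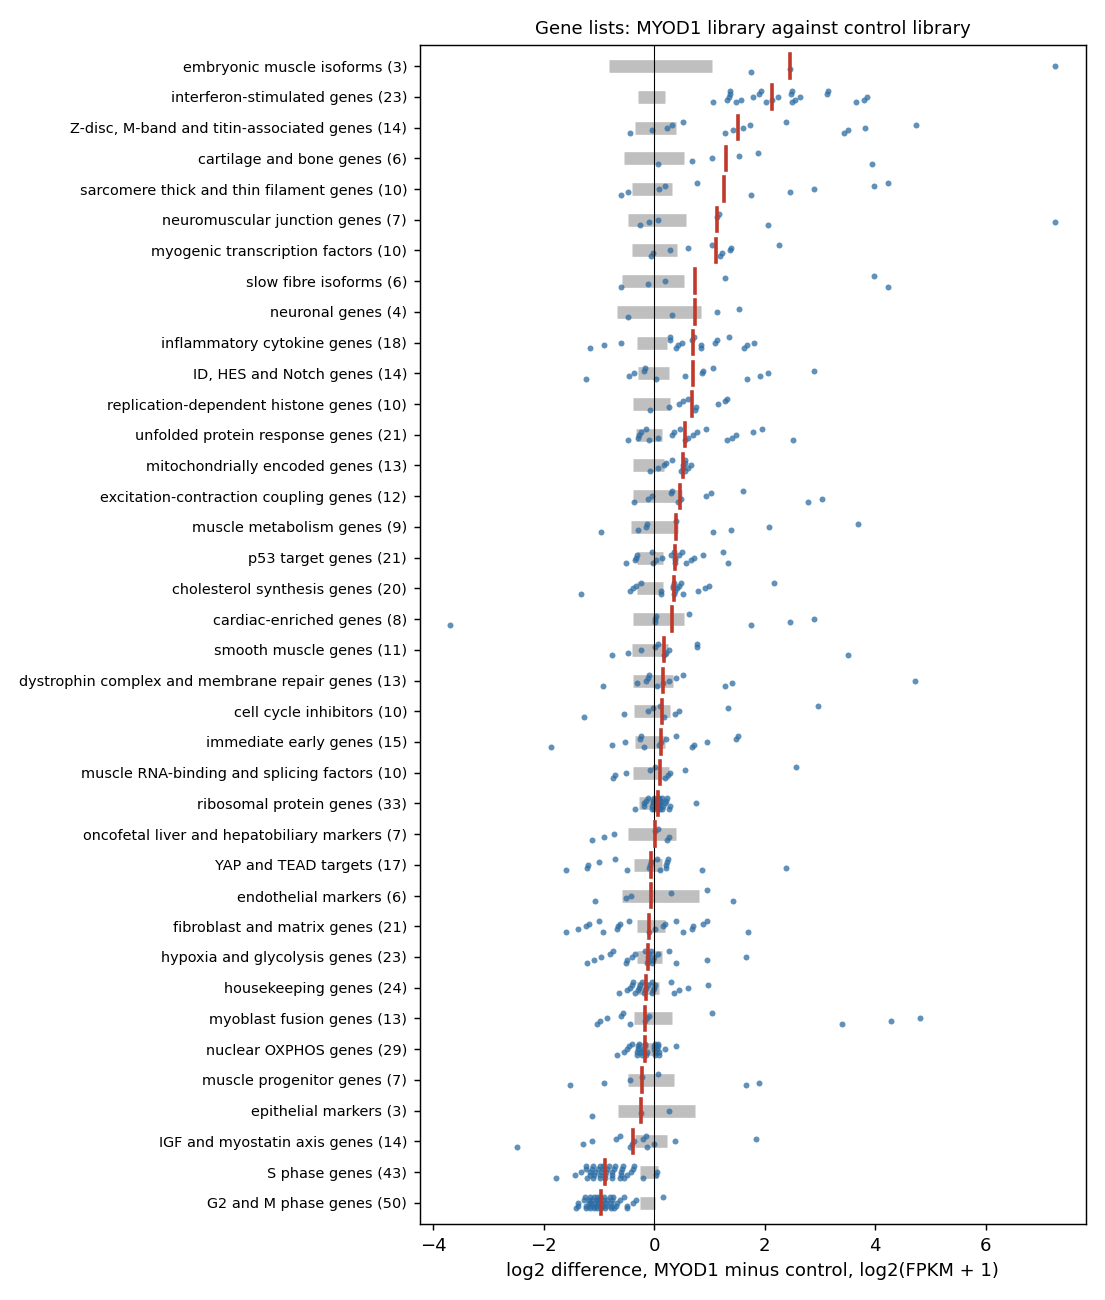
Log2 differences of log2(FPKM + 1), MYOD1 minus control, for the gene lists with at least 3 passing members (number in brackets); points are genes, red bars medians, and grey bars the central 95% of medians of 10000 expression-matched random lists. The interferon-stimulated median of 2.13 and the G2 and M phase median of -0.97 lie outside their grey bars.

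Interferon-stimulated genes were higher together. All 23 passing members of the list of 28 were at least 2-fold higher, with a median of 2.13 (percentile 100), where 95% of random lists lay between -0.30 and 0.19. Among the 122 protein-coding genes at least 4-fold higher, 13 were members, against 0.27 expected from independent lists. ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014540, plus strand), a ubiquitin-like modifier, was at 40.0 FPKM in the control library and 592 in the MYOD1 library, a 14.8-fold difference (13.6 to 16.1). IFI6 was 14.2-fold higher (13.1 to 15.5), and OAS2, a sensor enzyme for double-stranded RNA, 18.9-fold higher (17.0 to 21.1). The mitochondrial read share was higher in the same library, at 8.05% against 5.40%, and scaled without mitochondrial reads the median was 2.19.

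Inflammatory cytokine genes had a median of 0.71 (percentile 100), with 6 of 18 higher, 1 lower and 11 neither. ICAM1 was 4.38-fold higher (3.68 to 5.23), IL1A 3.75-fold (3.10 to 4.56) and CSF1 3.69-fold (3.25 to 4.21), while the NF-kappaB inhibitor TNFAIP3 was 2.43-fold lower (2.19 to 2.71). Unfolded protein response genes had a median of 0.56 (percentile 100), with 6 of 21 higher and 15 neither; HERPUD1 was 6.07-fold higher (5.69 to 6.48), DNAJB9 4.37-fold (3.79 to 5.06) and CHAC1 4.42-fold (3.49 to 5.64). Immediate early genes had a median of 0.12 (percentile 93.4), with 2 of 15 higher, 1 lower and 12 neither. EGR1 was 2.90-fold higher (2.76 to 3.05), ATF3 3.14-fold (2.78 to 3.56) and NR4A1 2.98-fold (2.38 to 3.74), and FOS was 4.05-fold lower (3.58 to 4.58).

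YAP and TEAD targets had a median of -0.05 (percentile 68.6), which was 0.0056 with the median gene set to 0, with 1 of 17 higher, 3 lower and 13 neither. ANKRD1, also a titin-associated gene of striated muscle, was 5.28-fold higher (5.11 to 5.46) at 775 FPKM, whereas F3, tissue factor, was 3.12-fold lower (2.89 to 3.39), AXL 2.35-fold lower (2.27 to 2.44) and CRIM1 2.34-fold lower (2.26 to 2.43). Hypoxia and glycolysis genes had a median of -0.11 (percentile 39.8), with 1 of 23 higher, 2 lower and 20 neither; PFKP was 2.36-fold lower (2.27 to 2.45), ADM 2.17-fold lower (2.01 to 2.35) and LDHA 2.05-fold lower (1.88 to 2.23), and the glucose transporter gene SLC2A3 3.46-fold higher (3.19 to 3.75). Cholesterol synthesis genes had a median of 0.36 (percentile 99.95), with 1 of 20 higher, 1 lower and 18 neither. INSIG1 was 4.72-fold higher (4.38 to 5.10) and MSMO1 2.04-fold higher (1.89 to 2.20).

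Lists of basic cell functions held no member at least 2-fold higher or lower on this scale, except histones. Nuclear OXPHOS genes had a median of -0.17 (percentile 25.0) over 29 members, NDUFS1 being 2.40-fold lower in FPKM (1.96 to 2.95), ATP5PB 1.48-fold (1.41 to 1.55) and SDHA 1.76-fold (1.43 to 2.17). The 13 mitochondrially encoded genes had a median of 0.52 (percentile 99.97), with MT-CO1 1.59-fold higher (1.58 to 1.59), MT-ND6 1.53-fold (1.48 to 1.58) and MT-CYB 1.48-fold (1.46 to 1.49). Ribosomal protein genes had a median of 0.08 (percentile 98.95) over 33 members, 0.14 with the median gene set to 0 and close to 0 in TPM. These scalings multiply all values of a library by the same factor, but with the pseudocount they move low and high values differently. RPL28 was 1.22-fold higher (1.19 to 1.25) and RPL3 1.20-fold higher (1.18 to 1.22). Housekeeping genes had a median of -0.16 (percentile 32.5) over 24 members, with TBP 1.64-fold lower (1.39 to 1.94) and SNRPD3 1.42-fold lower (1.24 to 1.63). Replication-dependent histone genes had a median of 0.68 (percentile 99.9), with 3 of 10 higher and 7 neither; H4C8 was 2.76-fold higher (2.34 to 3.26), H2BC4 2.53-fold (1.78 to 3.64) and H4C5 4.91-fold (1.60 to 20.1). The list holds histone genes whose mRNA lacks a poly(A) tail, and some are close copies whose reads cannot be assigned with certainty.

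The largest differences among abundant protein-coding genes lay partly outside the lists. After MYOD1, the 10 largest included NGFR, the p75 neurotrophin receptor, with 3 reads in the control library and 163 FPKM in the MYOD1 library (ratio 3849, 1317 to 18667), and CHRNA1. SPNS2, a sphingosine-1-phosphate exporter, was at 79.5 FPKM against 3 control reads (ratio 1841, 630 to 8929). ELOVL3, a fatty acid elongase, was 62.9-fold higher (43.9 to 93.5), and NES, the intermediate filament nestin of muscle and neural progenitors, was at 27.0 FPKM against 0 (at least 856-fold higher). The homeobox gene NKX3-2 was 36.6-fold higher (27.8 to 49.2). ITGA7, KLHL41 and DYSF completed the set. In the other direction, HAS3 (ENSG00000103044, chromosome 16, 69105653 to 69118719, plus strand), a hyaluronan synthase, was at 21.8 FPKM in the control library and 0.34 in the MYOD1 library, 64.4-fold lower (43.8 to 98.8).

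The 10 smallest differences also included transporter genes, among others, and no shared function was tested. The vesicular acetylcholine transporter gene SLC18A3 was at 227 FPKM in the control library and 22.2 in the MYOD1 library, 10.2-fold lower (9.49 to 10.99). The fatty acid transporter gene SLC27A2 was 18.2-fold lower (13.2 to 25.6), the aminopeptidase gene ANPEP 9.93-fold lower (9.18 to 10.8) and SFRP1, a Wnt antagonist, 7.61-fold lower (7.19 to 8.07). EVA1A, RGS4, ANGPTL4 and ARHGDIB were 7.82-fold, 8.25-fold, 8.74-fold and 7.06-fold lower, and NPPB was the remaining member. Of the 146 named genes, 46 share their span with an expressed gene on the opposite strand, such as NGFR with NGFR-AS1, and 18 with another on the same strand, such as SLC18A3 with CHAT. Whether reads were counted by strand is not given in the sources used here, so values of these genes are less certain.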

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

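Primary chromosomes only, scaling without mitochondrial reads, at least 20 reads and removal of GC and length trends were chosen after seeing the data, and the other settings before. Depth limits genes with few reads, and 1 library per group leaves culture-to-culture variation unmeasured. Of list medians under alternative settings, 372 moved by less than 1.5-fold, 34 moved by more with the same sign and 2 moved by more and turned sign, while 17 of all 408 had the opposite sign to the main setting; of differences of named genes, 1272 moved by less and 134 by more; of list percentiles without expression matching, 38 were similar and 3 moved. Changing the pseudocount, the filter or the unit changes how far low values count, and no other cause was tested. With the lists joined as above, the muscle median exceeded that of the other lineages in the main setting and in all 10 alternatives. No alternatives are given for the wider muscle grouping, whose median was 0.28. Fast fibre isoforms and hepatocyte markers had no passing member, so no median of theirs, nor a difference from the fast fibre list, was compared; adipocyte genes gave no value with a filter of 5 FPKM.

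The MYOD1 difference was 12.47 at a pseudocount of 0.1, 6.84 at 5 and 10.78 in TPM. Rows at least 4-fold higher and lower numbered 770 and 381 at a pseudocount of 0.1, 56 and 12 at 5, 604 and 320 in TPM, 122 and 26 for protein-coding genes, and 1062 and 674 at a size of 2-fold. Lower rows numbered 111 with GC and length trends removed, among rows with a GC value only, and 42 with at least 20 reads. All 205 higher and 71 lower rows stayed past 4-fold in TPM, 205 and 67 with the median gene set to 0, and 56 and 12 at a pseudocount of 5.

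At a pseudocount of 0.1, medians were 2.70 for sarcomere, 3.61 for Z-disc, 5.52 for embryonic, 2.07 for slow fibre, 4.18 for muscle non-coding, 1.37 for neuronal and 2.25 for cartilage and bone genes; embryonic exceeded slow fibre genes by 3.45 and Z-disc exceeded smooth muscle genes by 3.42. At a pseudocount of 5 they were 0.47 for myogenic factors, 0.65 for sarcomere, 0.46 for Z-disc, 0.93 for embryonic, 0.32 for neuromuscular junction, 1.47 for muscle non-coding and 0.59 for cartilage and bone genes, and the list differences were 0.65 and 0.35. In TPM, sarcomere genes were at 1.88, Z-disc at 2.55, embryonic at 3.90, muscle non-coding at 3.30 and cartilage and bone genes at 2.01, with list differences of 2.61 and 2.44.

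Without a filter, medians were 0.45 for myogenic factors, 0.083 for sarcomere, 0.086 for Z-disc, 1.01 for embryonic, 0.074 for slow fibre, 0.23 for neuromuscular junction, 1.17 for muscle non-coding, 0.020 for neuronal, 0.69 for cartilage and bone and 0.047 for leukocyte genes, the last with a turned sign; list differences were 0.93 and 0.015. With a filter of 5 FPKM they were 0.49 for sarcomere, 2.39 for Z-disc, 7.25 for embryonic (1 gene), 0.065 for neuromuscular junction, -0.75 for endothelial, -0.074 for neuronal (a turned sign) and -1.99 for leukocyte genes, with list differences of 7.05 and 2.27. Smaller medians also crossed 0 without moving by 1.5-fold, among them YAP and TEAD targets at 0.04 and endothelial markers at 0.03 with GC and length trends removed, oncofetal markers at -0.33, epithelial markers at 0.27, muscle metabolism genes at -0.14 and muscle RNA-binding genes at -0.077 with a filter of 5 FPKM, oncofetal markers at -0.04 in TPM, and progenitor genes at 0.01, adipocyte genes at 0.06 and epithelial markers at 0.03 without a filter.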

Other observations

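The groups of genes and the tests in this part were chosen after the results were seen. Among all 10315 passing protein-coding genes, 527 were at least 2-fold higher and 332 at least 2-fold lower, and 4 transcription factor families, picked after their values were seen, are given beside this with no test. C2H2 zinc finger genes had 2 higher and 1 lower of 365 passing members. Homeobox genes had 7 higher and 0 lower of 65 passing members, among them NKX3-2, HOXB9 and SIX4. Basic helix-loop-helix genes had 7 higher and 2 lower of 43, the higher ones including the forced gene MYOD1 itself, with HEYL, BHLHE40, ID2 and MYCL higher and ID1 and MXD3 lower. Basic leucine zipper genes had 5 higher and 1 lower of 40, BATF2, ATF3, JUND, DDIT3 and CEBPD being higher and FOS lower. Among long non-coding RNA genes, LINC02544 had 3 reads in the control library and 36.5 FPKM in the MYOD1 library, LINC01293 was at 42.6 FPKM in the control library and 10.8 in the MYOD1 library, and MYOSLID, described as a smooth muscle transcript, at 6.72 and 1.30 FPKM.

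Values of a few antigen presentation genes outside the sparse chromosome 6 region, picked after they were seen, are given without a count or test. CIITA, the master regulator of class II genes, was at 1.32 FPKM in the control library and 0.19 in the MYOD1 library, and its target CD74 at 33.0 and 7.56 FPKM. NLRC5, which regulates class I genes, was at 1.11 and 3.38 FPKM, B2M at 50.9 and 100.4 FPKM, and PSMB10 at 1.55 and 4.71 FPKM. The RNA sensor gene TLR3 was at 0.49 and 2.22 FPKM. Interferon genes themselves were near the detection limit: IFNB1 had 1 and 0 reads, IFNL1 3 and 1, IFNL2 0 and 6, and IFNG 0 and 0.

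The interferon-stimulated genes, which were higher in the MYOD1 library, may reflect MYOD1, the vector or the culture. Their median stayed at 2.19 with the median gene set to 0 and at 2.18 with GC and length trends removed. The first setting cannot decide on library scaling, because the median difference over passing genes was only -0.03 and it could move the list little. If the median gene was equal in the 2 cultures, which was not tested, the second value argues against those trends as the whole cause. A difference between cultures or vectors unrelated to MYOD1 cannot be told apart from an effect of MYOD1, because each group had 1 culture. The nearest value, the median of the inflammatory cytokine genes, was 0.71 and does not decide. That forced MYOD1 expression is accompanied by an interferon response in this line remains a hypothesis that independent transductions would test.

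Several muscle genes were high in the MYOD1 library while MYOG and others were near 0. Depth is not the limit for MYOG, whose upper 95% limit was 0.46 FPKM. Whether the source was a few fully differentiated muscle cells among unconverted ones stayed open. Of 12 transcripts abundant in myotubes, 0 reached 0.1 times the CHRNA1 level of 154 FPKM, and their median was 0.22 FPKM. The 12 were picked after their values were seen, so this count cannot decide. TNNC1 came close at 14.8 FPKM, and TNNI1, not among them, was at 17.8 FPKM. Among genes fixed beforehand, no fast fibre isoform exceeded 0.82 FPKM, DES was at 0.38 FPKM and CKM had 0 reads in the MYOD1 library. Reads lost to near-identical copies leave MYOG unexplained, as they do 8 other single-copy genes among the low ones, whose median was 0 FPKM. Both libraries were collected after 12 days, so MYOG levels at earlier times were not measured. That MYOD1 targets such as CHRNA1 and MYMX may be expressed with little MYOG is a hypothesis that values from single cells at several times would test.

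Cell cycle genes were lower in the MYOD1 library by a median of -0.93. The median was -0.88 with the median gene set to 0 and -0.91 with GC and length trends removed. If the median gene was equal in the 2 cultures, which was not tested, the second value argues against those trends as the whole cause. The median difference over passing genes was only -0.03. Setting the median gene to 0 could therefore move the list little and cannot decide on library scaling. A difference in cell density between the cultures cannot be told apart from cell cycle exit after MYOD1, since the design holds 1 culture per group. CDKN1A was 2.53-fold higher, which either explanation could give. The fraction of cycling cells was not measured.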
